A study of Coryphaena hippurus with 32 samples.

How the data were processed

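RNA of whole embryos or larvae, 30 pooled animals per replicate per the labels' protocols, was made into TruSeq libraries and sequenced on an Illumina HiSeq2500, per the labels and the series' design text. Replicates are samples the labels name as separate, kept in replicate beakers per the labels' protocols. Nothing beyond the labels says that they came from separate spawns, so p-values measure the spread between these samples. The count table holds whole-number counts per table line, deposited without normalization, in 42538 lines keyed to human Entrez gene identifiers. HTSeq, DESeq2 and the human build hg19 are named, without versions or roles, in the submitters' processing notes. How mahi-mahi reads were assembled or aligned and then tied to human genes is not given in the sources used here. The authors' deposited comparison tables of each oil against control hold, per the file headers, a log2 fold change with its standard error and a mean of size-factor-normalised counts. Per the file headers they also hold a Wald score (the log2 change over that error), a p-value and an adjusted p-value. From those tables only gene symbols, these means and the counts of called genes were used. A mahi-mahi genome and coordinates were not used here.

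Human identifiers stand for the best-matching human gene, so paralogs that fish carry in several copies can share 1 symbol or be split over several lines. Counts of opsins, crystallins, globins, cytochromes P450 and other families are uncertain in this way. Of 12653 identifiers, 5654 had more than 1 distinct line (up to 80). The line with the highest total was kept for each gene. This was decided after the files were seen, because its mean matched the authors' deposited means for genes with several lines (median ratio 1.01, against 2.03 for the sum of the lines). In 11% of tested genes, and in 25 of 230 named results against control, the kept line's mean still lay over 1.5-fold from the deposited one, so the deposited change is not that of the kept line. These include CA4 (286 against 3.63), COL9A3 (649 against 0.349) and MATN3 (148 against 3.48) in source. They also include HSP90AB1, P4HA1, RHBG, RHCG, COL11A2, CASQ2, CRYBB2, CRYGB, PRDX1 and, in slick at 96 hpf, IGFBP1. The call counts under both were known when it was decided, and both are printed. Identifiers with identical counts in all samples were joined into 1 feature (256 identifiers in 103 features, such as MPO/EPX). Symbols came from the authors' deposited tables for 12210 identifiers, and 443 had none and are shown as ID and the number. Features without a symbol held 10.8% of counts. Lines without an identifier (332, at most 0.043% of a sample's counts) were left out, and 10998 features had a count.

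Samples of 1 group were compared pairwise by a chi-square test over genes with at least 20 counts. A total of 5 pairs of control samples did not differ beyond sampling noise at a p threshold of 0.001 (chi-square per degree of freedom 0.968 to 1.03, p from 0.021 to 0.98), whereas the other 41 pairs differed (1.18 to 3.03, p at most 2.1e-26). That threshold was set after the files were seen. Such a pair was summed and counted as 1 library, so that the fits used 27 libraries, not the 32 samples planned. Over 1 line per gene a deposited sample held 1823727 to 2560303 counts, and a summed pair up to 4470040, which sets the precision for low genes.

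Gene tests used edgeR 4.0.16 in R 4.3.3: TMM scaling, the low-count filter filterByExpr, a quasi-likelihood F-test (two-sided) and a call at a Benjamini-Hochberg adjusted p below 0.05. Oil against control and slick against source were fitted within a stage over its 9 libraries (6 residual degrees of freedom, common biological coefficient of variation 3.82%, 4.29% and 4.14% at 24, 48 and 96 hpf). Interactions between stages and development of controls were fitted over all 27 libraries (18 residual degrees of freedom, 4.12%). A list of 789 genes in 31 groups was fixed beforehand, of which 578 genes had a line. Lists with at least 5 measured members were tested, two-sided, with camera in limma 3.58.1 (preset correlation 0.01, prior count 2), adjusted over the lists of a comparison, and again with an estimated correlation and with fry. A count adjusted over the list alone uses the unadjusted p-values of its members only. The designs, lists, alternatives and the naming rule were chosen before the data were examined. For each oil against control that rule named CYP1A1, CYP1A2, CYP1B1, AHRR and TIPARP where tested. It named the 5 called genes with the highest and the 5 with the lowest change (3 and 3 in other comparisons) among those with a mean normalised count of at least 50 and groups that did not overlap. It named up to 4 called members with the lowest p (2 in other comparisons) of each list called by camera or with 3 or more called members. CYP1A2 and TIPARP had no tested line. Some genes that the rule names are not reported here. A fold against a group at 0 was bounded with 3 counts over the group. Intervals and floors cover counting error only.

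Alternatives were RLE scaling, no low-count filter, a robust fit, all libraries in 1 fit, the 2 groups compared alone, 1 surrogate variable (sva 3.50.0), DESeq2 1.42.0, a replicate block and leaving out each library in turn. Chosen after the data were seen were the 32 samples as deposited and the sum of a gene's distinct lines. The choice of scaling was first tested by the median change of all genes, which TMM centres near 0, and that test was replaced by a fit scaled to total counts alone after its value was seen. The fits were tested on simulated counts with 200 changed genes. For slick against control at 96 hpf, 29.9%, 67.2% and 84.8% of genes changed 1.25-fold, 1.5-fold and 2-fold were recovered among 8511 genes, with 6 false calls. Recovery was lower for slick against control at 24 hpf, with 16.4%, 50.7% and 72.7% among 7757 genes. In the 4 interactions 20.9% to 28.4% of genes changed 1.5-fold were recovered. For the slick interaction from 48 to 96 hpf 11% of calls among 8898 genes were false. In the authors' deposited tables an adjusted p below 0.05 was found for 18, 158 and 1184 genes in slick at 24, 48 and 96 hpf and for 49, 127 and 95 in source. Of these 13, 144, 1114, 36, 65 and 55 were also called here. Those tables list 12538 genes but give an adjusted p for 627, 4921 and 8205 in slick and 627, 1700 and 1708 in source. The deposited counts therefore rest on unlike numbers of genes, and are not like for like between stages, oils or with the calls here.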

Results

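The series measured messenger RNA by sequencing in whole embryos and larvae of mahi-mahi (Coryphaena hippurus), a fast-growing pelagic fish, at 24, 48 and 96 h post fertilization (hpf). Freshly fertilized embryos were kept in seawater without oil or with a high-energy water accommodated fraction, a mixture of seawater and dispersed oil, made from Deepwater Horizon slick oil or source oil. The labels give a concentration of 0 g/l for controls and 1 g/l for both oils. Hydrocarbon levels in the water were not used here, so dose and type of oil cannot be told apart where slick is compared with source. Oil collected as slick had weathered at sea, whereas source oil came from the well. The 32 deposited samples held 5 pairs of control samples whose counts did not differ beyond sampling noise at a p threshold of 0.001 (chi-square per degree of freedom from 0.968 to 1.03, p from 0.021 to 0.98, against 1.18 to 3.03 in the other 41 pairs within groups). Each such pair was counted as 1 sample: replicates 4 and 5, 6 and 7, and 8 and 9 of the 48 hpf controls, and replicates 10 and 11, and 12 and 13 of the 96 hpf controls. This left 27 libraries, with n = 3 in each of the 9 groups. Total counts per deposited sample ranged from 5425111 to 8884058 over all lines of the count table, and from 1823727 to 2560303 over the 1 line kept per gene. Between 9992 and 10468 genes had a count in each sample. Fold changes below are ratios of normalised counts. Adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Errors are SD with n = 3 unless a log2 change is given with its standard error.

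The aryl hydrocarbon receptor (AhR) battery lists targets of the receptor that binds polycyclic aromatic hydrocarbons. Of its members 3 of 5, 3 of 7 and 4 of 8 were called higher in slick at 24, 48 and 96 hpf, and 1 of 5, 3 of 7 and 4 of 8 in source. Camera called the list in each case, and with an estimated correlation it held in slick but not in source (adjusted p = 0.14, 0.1 and 0.18). CYP1A1, the monooxygenase that oxidises these hydrocarbons, was higher in slick than in control embryos by 22.1-fold at 24 hpf (1896 ± 133 normalised counts against 85.3 ± 17.4, adjusted p = 8.6e-99). The slick increase was 30.3-fold at 48 hpf (4460 ± 234 against 147 ± 11.5, adjusted p = 2.1e-48) and 35.9-fold at 96 hpf (3998 ± 367 against 111 ± 17.5, adjusted p = 1.5e-103). Source oil raised CYP1A1 7.72-fold (661 ± 40.7, adjusted p = 3.7e-66), 10.3-fold (1517 ± 59.1, adjusted p = 1.4e-39) and 11.4-fold (1271 ± 111, adjusted p = 3.7e-78) at the same stages. Slick exceeded source directly by 2.87-fold at 24 hpf, 2.94-fold at 48 hpf and 3.14-fold at 96 hpf (adjusted p = 1.2e-57, 6.4e-29 and 1.8e-55). AHRR, the repressor that the receptor itself induces, rose 11.6-fold in slick at 48 hpf (204 ± 12.2 against 17.6 ± 3.71, adjusted p = 5.8e-25) and 7.89-fold at 96 hpf (321 ± 33.6 against 40.7 ± 2.71, adjusted p = 2.4e-51). Its increase in source was 3.41-fold at 48 hpf and 2.76-fold at 96 hpf (adjusted p = 7.7e-08 and 5.6e-15). At 24 hpf AHRR was 2.81-fold higher in slick (17.2 ± 2.02 against 6.03 ± 1.54, adjusted p = 0.031), a call lost in each of the 6 fits that left out 1 library. In source it was 1.66-fold higher without passing the test (adjusted p = 0.51). FOXQ1, a forkhead transcription factor, was 2.36-fold, 2.01-fold and 3.34-fold higher in slick at the 3 stages, and 1.49-fold and 1.74-fold higher in source at 48 and 96 hpf. CYP1B1, a related monooxygenase, was 14.1-fold higher in slick at 96 hpf (42.6 ± 9.18 against 2.86 ± 1.92, adjusted p = 4.7e-18) and 4.01-fold in source (adjusted p = 0.0087). FOXQ1 in source at 48 hpf and CYP1B1 in source at 96 hpf lost their calls when 1 library was left out and when all table lines of a gene were summed. Reads of related CYP1 genes cannot be told apart in a table keyed to human genes, so each symbol may hold more than 1 mahi-mahi gene. Its values come from the 1 line kept.

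**Figure D1:**
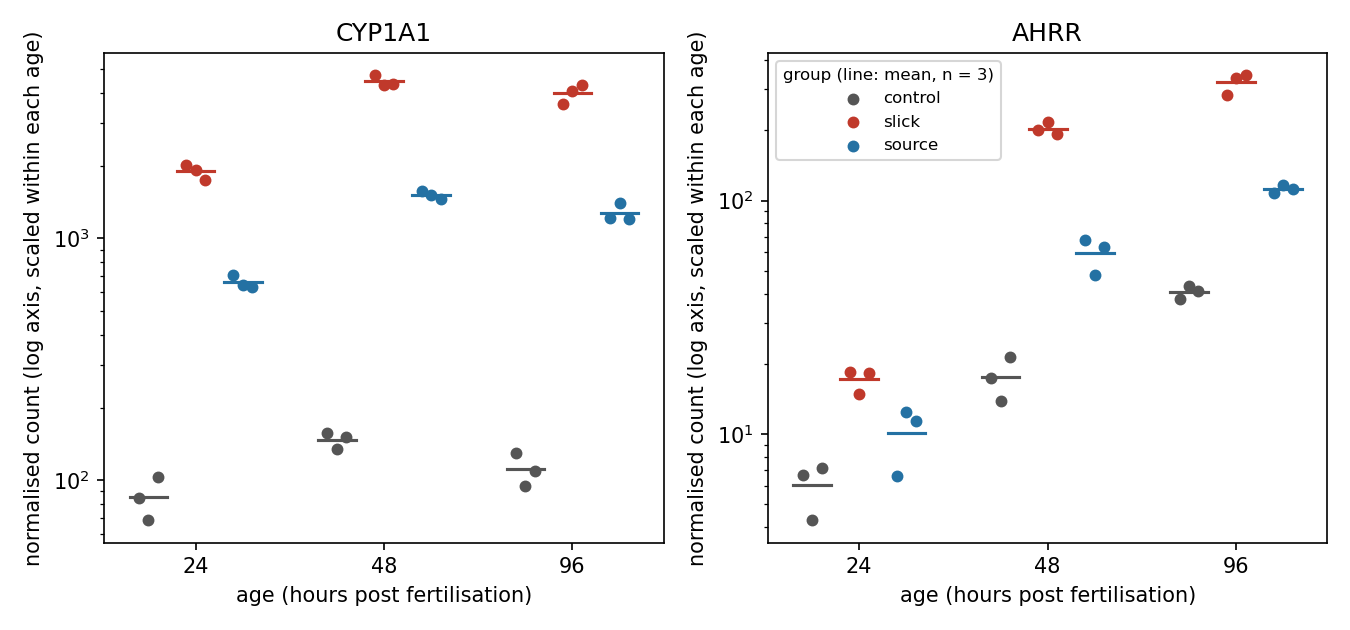
Normalised counts (log axis, scaled within each stage) of CYP1A1 and AHRR in each library of the control, slick and source groups at 24, 48 and 96 hpf, each point 1 library and each line the mean of the 3 libraries of a group. At 96 hpf the CYP1A1 counts of the slick libraries lie between 3596 and 4314, those of the source libraries between 1199 and 1399 and those of the controls between 94.7 and 129.

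The effect of slick oil on 24 hpf embryos was small outside the AhR genes. Genes with higher counts included SRM, the spermidine synthase of polyamine metabolism (1.68-fold, 152 ± 16.8 against 91.0 ± 18.7, adjusted p = 1.4e-05). NPC1, a lysosomal cholesterol transporter (1.69-fold, 65.4 ± 4.32 against 38.7 ± 8.32, adjusted p = 0.013), KCNQ1, a potassium channel (1.66-fold, adjusted p = 0.013), and MST1 (1.6-fold) were higher too. Lower counts were found for CYLD, a deubiquitinase (0.706-fold, 299 ± 25.8 against 424 ± 41, adjusted p = 2.1e-06), BCO1, which cleaves beta-carotene (0.722-fold, 304 ± 22.8 against 422 ± 14.8, adjusted p = 6.2e-06), and BROX (0.676-fold). In the AhR battery 3 of 5 measured members rose and 2 were not called (camera adjusted p = 2.4e-08; adjusted p = 0.024 with an estimated correlation). Of 61 cytosolic ribosomal protein genes 5 fell, among them RPS3A at 0.892-fold and RPS14 at 0.891-fold, and 56 were not called. In that list 34 fell when adjusted over the list alone (median log2 change -0.11, camera adjusted p = 2.7e-09; adjusted p = 0.52 with an estimated correlation). None of 7 lens genes was called, 1 fell adjusted over the list alone, and the list's median was -0.30 (camera adjusted p = 0.016; adjusted p = 0.47 with an estimated correlation). For 32 oxidative phosphorylation genes, 0 of which were called, the median was -0.07 (camera adjusted p = 0.008; adjusted p = 0.51 with an estimated correlation). The other 25 of 29 tested lists were not called, among them 27 calcium handling and cardiac ion channel genes (1 higher, camera adjusted p = 0.77) and 14 cardiac sarcomere genes (0 called, camera adjusted p = 0.19). Across 7757 genes, edgeR called 24 higher and 21 lower. Of these genes 653 had an unadjusted p below 0.05, and 12.9% had groups that did not overlap, against 10% by chance. The count of 45 fell to 21, 26 and 24 without control replicates 1, 2 and 3, to 16 without slick replicate 1 or replicate 2. It fell to 32 with DESeq2 (5 higher and 27 lower), to 18 with all stages in 1 fit and to 6 with the table lines of each gene summed. NPC1, KCNQ1, MST1, BROX, RPS3A and RPS14 lost their calls with 1 library left out, and summing the lines also ended those of SRM and FOXQ1.

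Source oil at 24 hpf raised CA4, a membrane carbonic anhydrase (1.76-fold, 365 ± 51.5 against 207 ± 3.95, adjusted p = 2.1e-13) and IGFBP1, a secreted binder of insulin-like growth factors (1.75-fold, 70.3 ± 7.96 against 40.2 ± 3.72, adjusted p = 0.0014). ETNPPL, which breaks down phosphoethanolamine (1.73-fold, adjusted p = 5.2e-05), and SRM (1.66-fold, 151 ± 9.53, adjusted p = 1.1e-05) were higher as well. DDX42, an RNA helicase (0.671-fold, 68.4 ± 2.98 against 102 ± 9.67, adjusted p = 0.0067), MEFV (0.674-fold) and RNF20, a histone ubiquitin ligase (0.728-fold), were lower. Of 15 hypoxia genes 3 rose, namely NDRG1 (1.43-fold, 310 ± 14.9 against 217 ± 13.6, adjusted p = 6.6e-06) and the prolyl hydroxylase subunits P4HA1 (1.23-fold) and P4HA2 (1.3-fold). In that list 5 rose adjusted over the list alone (median log2 change 0.31, camera adjusted p = 0.00041; adjusted p = 0.15 with an estimated correlation). In the AhR battery 1 of 5 members rose (camera adjusted p = 0.00028; adjusted p = 0.14 with an estimated correlation). Among 61 ribosomal protein genes 16 fell, such as RPL24 (0.849-fold, adjusted p = 5.7e-05) and RPL27A (0.875-fold), and 45 were not called. A total of 39 fell adjusted over the list alone (median -0.12, camera adjusted p = 2.1e-09; adjusted p = 0.55 with an estimated correlation). The replication helicase genes MCM2 (0.795-fold) and MCM5 (0.796-fold) fell, and the other 20 of 22 cell cycle genes were not called. In that list 4 fell adjusted over the list alone (camera adjusted p = 0.0048; adjusted p = 0.29 with an estimated correlation). Lists of 28 proteasome genes (median -0.10, camera adjusted p = 0.0033) and 32 oxidative phosphorylation genes (median -0.07, camera adjusted p = 0.045) were lower with 0 members called. Their adjusted p = 0.15 and 0.55 with an estimated correlation. The 7 lens genes were lower by camera (median -0.29, adjusted p = 0.0495), with 0 called and adjusted p = 0.43 with an estimated correlation. That lens call was also lost with RLE scaling (adjusted p = 0.051). In the heat shock list, not called by camera, the collagen chaperone SERPINH1 rose 1.3-fold while HSP90AB1 (0.891-fold) and HSP90AA1 (0.894-fold) fell. EdgeR called 77 genes higher and 54 lower. At this comparison 925 had an unadjusted p below 0.05, and 16.8% of genes had separate groups against 10% by chance. The count of 131 fell to 53 without control replicate 3, to 54 without source replicate 11. It fell to 84 with DESeq2 (14 higher and 70 lower) and to 44 with summed lines. DDX42, MEFV, RNF20, P4HA2, MCM2, MCM5, HSP90AB1 and HSP90AA1 lost their calls with 1 library left out, and RPL27A and SERPINH1 theirs with summed lines.

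Slick and source embryos compared directly at 24 hpf differed in CYP1A1 (above) and KCNQ1, which was 2.54-fold higher in slick (72.5 ± 14.4 against 28.5 ± 7.15, adjusted p = 3.7e-08). CHAC1, which degrades glutathione (0.61-fold, adjusted p = 1.1e-07), was lower in slick. In the AhR battery 1 of 5 members was higher and 3 adjusted over the list alone (camera adjusted p = 0.00055; adjusted p = 0.14 with an estimated correlation). Camera also placed 11 eye development genes (median 0.20, adjusted p = 0.011), 28 proteasome genes (0.07, adjusted p = 0.006) and 22 cell cycle genes (0.15, adjusted p = 0.024) higher in slick and 15 hypoxia genes lower (-0.19, adjusted p = 0.027), with 0 members of each called. These calls were lost, with adjusted p = 0.14, 0.14, 0.43 and 0.43 with an estimated correlation. EdgeR called 3 genes higher and 14 lower in slick, with 591 at an unadjusted p below 0.05. The count of 17 became 11 without slick replicate 3 or source replicate 10, and 4 without source replicate 11. It was 5 with DESeq2, 10 with all stages in 1 fit and 3 with summed lines.

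Slick oil at 48 hpf raised the ammonia channel genes RHCG (2.99-fold, 87.8 ± 3.17 against 29.4 ± 3.47, adjusted p = 3.8e-10) and RHBG (2.52-fold, 199 ± 3.94 against 79.0 ± 6.55, adjusted p = 6.2e-14). The extracellular matrix gene CRTAC1 rose 2.68-fold (140 ± 4.13 against 52.4 ± 9.44, adjusted p = 1.6e-11). G6PC, the glucose-6-phosphatase of gluconeogenesis (0.566-fold, 187 ± 19.9 against 331 ± 24.6, adjusted p = 3.8e-10), QSOX1 (0.583-fold), ITGBL1 (0.584-fold) and UCP1, a mitochondrial carrier (0.586-fold), were lower. Liver secreted proteins fell, with the retinol carrier RBP4 at 0.709-fold (1356 ± 84.5 against 1913 ± 38.3, adjusted p = 6.6e-10), transferrin (TF) at 0.725-fold and APOB, the lipoprotein scaffold, at 0.688-fold. Of 14 members 6 were called, 8 were not, and 7 fell adjusted over the list alone (median log2 change -0.34, camera adjusted p = 1.6e-06; adjusted p = 0.15 with an estimated correlation). Of 10 heat shock genes 4 rose, including HSP90AA1 (1.21-fold), HSP90AB1 (1.16-fold) and DNAJB1 (1.62-fold). In that list 5 rose with 1 lower adjusted over the list alone (camera adjusted p = 0.013; adjusted p = 0.18 with an estimated correlation). In the NRF2 oxidative stress list 3 of 13 genes rose, namely PGD (log2 change 0.32), SQSTM1 (1.5-fold) and GCLC, the rate-limiting glutathione synthesis subunit (1.32-fold), while thioredoxin (TXN) fell to 0.81-fold. Adjusted over the list alone 4 were higher and 2 lower (camera adjusted p = 0.013; adjusted p = 0.15 with an estimated correlation). In the AhR battery 3 of 7 members rose, and 4 adjusted over the list alone (camera adjusted p = 1.2e-08; adjusted p = 0.02 with an estimated correlation). Cholesterol biosynthesis had 1 of 19 members higher, MSMO1 (1.53-fold, adjusted p = 3.3e-06), and 2 adjusted over the list alone (camera adjusted p = 0.013, and 0.33 with an estimated correlation). Without slick replicate 4, a test chosen after the result was seen, the cholesterol list was not called (camera adjusted p = 0.16). The neuronal list had 1 of 18 members higher (camera adjusted p = 0.031; adjusted p = 0.24 with an estimated correlation). The 7 phototransduction genes had a median of -0.32 with 0 called and 1 lower adjusted over the list alone (camera adjusted p = 0.013; adjusted p = 0.33 with an estimated correlation).

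In other lists that camera did not call in slick at 48 hpf, single members passed the test. The collagen genes COL1A1 (0.719-fold, adjusted p = 9e-11) and COL1A2 (0.785-fold) and the matrix gene SPARC (0.815-fold) were among 5 lower members of 19 cartilage and bone genes, with 1 higher (camera adjusted p = 0.28). The succinate dehydrogenase subunits SDHB (1.46-fold, 1837 ± 86.9 against 1258 ± 32.8, adjusted p = 1.9e-11) and SDHA (1.19-fold) rose. In the calcium handling and cardiac ion channel list KCNQ1 (0.297-fold, 4.94 ± 1.34 against 16.8 ± 3.28, adjusted p = 0.003) and the sodium pump subunit ATP1B1 (0.79-fold) fell. The calcium channel genes CACNA1D (1.4-fold) and CACNA2D1 (1.32-fold) rose, and 23 of 27 members were not called (camera adjusted p = 0.12). Without slick replicate 4, a test chosen after the result was seen, camera called that list higher (median 0.2, adjusted p = 0.013). IGFBP2 (0.722-fold) and the gluconeogenic genes PCK1 (0.821-fold) and FBP1 (0.77-fold) were also lower. EdgeR called 119 of 8060 genes higher and 147 lower. Of all genes 1113 had an unadjusted p below 0.05, and 18.7% had separate groups against 10% by chance. The count of 266 fell to 170 without slick replicate 6, to 124 with DESeq2 and to 148 with summed lines. UCP1, CACNA1D, CACNA2D1, DNAJB1, FBP1, ITGBL1, PCK1, TXN and SDHA lost their calls with 1 library left out, and ATP1B1 its call with summed lines.

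Source oil at 48 hpf raised CACNA1D (1.64-fold, 150 ± 17 against 92.0 ± 6.73, adjusted p = 0.0001), RHBG (1.59-fold, 126 ± 8.59 against 79.0 ± 6.55, adjusted p = 0.00046) and CRTAC1 (1.63-fold, adjusted p = 0.0068). F13A1, the A subunit of clotting factor XIII (0.537-fold, 35.9 ± 4.96 against 67.3 ± 0.302, adjusted p = 0.0019), MTDH (0.634-fold), the hatching-type metalloprotease gene ASTL (0.636-fold, adjusted p = 7.1e-06) and CAPN9, a calpain (0.679-fold, adjusted p = 0.00019), were lower. Of 61 ribosomal protein genes 12 fell, such as RPS16 (0.807-fold) and RPL13 (0.86-fold), and 49 were not called. A total of 30 fell adjusted over the list alone (median log2 change -0.11, camera adjusted p = 5.3e-11; adjusted p = 0.46 with an estimated correlation). TF (0.848-fold), ITIH2 (0.843-fold) and RBP4 (0.87-fold) were the 3 lower members of 14 liver secreted proteins. Adjusted over the list alone there were 6 lower and 1 higher (camera adjusted p = 0.046; adjusted p = 0.51 with an estimated correlation). In the AhR battery 3 of 7 members rose (camera adjusted p = 7.9e-05; adjusted p = 0.1 with an estimated correlation). Camera placed the lens list (median 0.27, 6 of 10 higher adjusted over the list alone, adjusted p = 0.026) and the neuronal list (0.15, 4 of 18, adjusted p = 0.026) higher. It placed the oxidative phosphorylation (-0.10, 3 of 32 lower, adjusted p = 0.0036), cell cycle (-0.10, 2 of 22, adjusted p = 0.019), cardiac sarcomere (-0.10, 1 of 13, adjusted p = 0.019) and proteasome lists (-0.07, 0 of 28, adjusted p = 0.019) lower, with 0 members called over all genes. With an estimated correlation these had adjusted p = 0.64, 0.36, 0.46, 0.32, 0.64 and 0.28. The cartilage collagen genes COL9A3 (1.33-fold) and COL9A1 (1.31-fold) rose and COL1A1 (0.861-fold) fell in a list that camera did not call. EdgeR called 53 genes higher and 53 lower. In this test 1027 had an unadjusted p below 0.05, and 17.9% had separate groups against 10% by chance. The count of 106 fell to 34 without control replicate 4-5, to 41, 47 and 26 without source replicates 13, 14 and 15, to 57 with DESeq2 and to 34 with summed lines. It rose to 160 in a robust fit, 181 with the 2 groups alone and 182 with the 32 samples as deposited. CRTAC1, F13A1, COL1A1, RPS16, RPL13, TF, ITIH2 and RBP4 lost their calls with 1 library left out. ASTL lost its call in the robust fit and with summed lines. Lens genes also differed between the 48 hpf controls, with a median log2 difference from the 2 other libraries of -0.62 for replicate 6-7 and 0.66 for replicate 8-9.

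The direct comparison at 48 hpf placed AHRR (3.39-fold), CYP1A1 (2.94-fold), the ammonia channel gene RHAG (1.82-fold, 295 ± 31.7 against 162 ± 9.64, adjusted p = 1.3e-08) and SDHB (1.39-fold, adjusted p = 1.9e-08) higher in slick than in source. COL1A1 (0.836-fold), COL1A2 (0.848-fold), RBP4 (0.815-fold), COL7A1 (0.697-fold) and LOXL1 (0.712-fold) were lower in slick. HSP90AA1 (1.23-fold), HSP90AB1 (1.19-fold) and 1 further member of 10 heat shock genes were higher, with 7 adjusted over the list alone (camera adjusted p = 5.4e-05; adjusted p = 0.051 with an estimated correlation). With an estimated correlation the AhR battery (2 of 7 higher, 3 adjusted over the list alone, adjusted p = 0.036) and the proteasome list (0 of 28 called, 6 higher adjusted over the list alone, median 0.12, adjusted p = 0.036) kept their calls. The other 10 of the 13 lists that camera called did not. Of these 6 were higher in slick, namely NRF2 (2 of 13 members called), oxidative phosphorylation (1 of 32), cholesterol biosynthesis (1 of 19), cardiac sarcomere (1 of 13), ribosomal proteins (4 of 61) and the unfolded protein response (0 of 13). They had adjusted p = 0.16, 0.27, 0.33, 0.46, 0.41 and 0.41 with an estimated correlation. The 4 lower lists were cartilage and bone (6 of 19 called), liver secreted proteins (3 of 14), lens (0 of 10) and phototransduction (0 of 7), with adjusted p = 0.27, 0.22, 0.55 and 0.27 with an estimated correlation. Without slick replicate 4, a test of the lists chosen after the result was seen, the lens median went from -0.219 (camera adjusted p = 0.04) to -0.0404 (camera adjusted p = 0.73), and that of phototransduction from -0.197 to -0.215 (camera adjusted p = 0.014). The cholesterol and unfolded protein response lists were not called without it either (camera adjusted p = 0.25 and 0.29). EdgeR called 38 genes higher and 22 lower, with 814 at an unadjusted p below 0.05. The count of 60 became 116 without slick replicate 4 and 33, 39 and 36 without source replicates 13, 14 and 15. It was 37 with DESeq2, 100 in a robust fit, 110 without the low-count filter and 27 with summed lines. COL7A1 and LOXL1 lost their calls with 1 library left out.

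**Figure D2:**
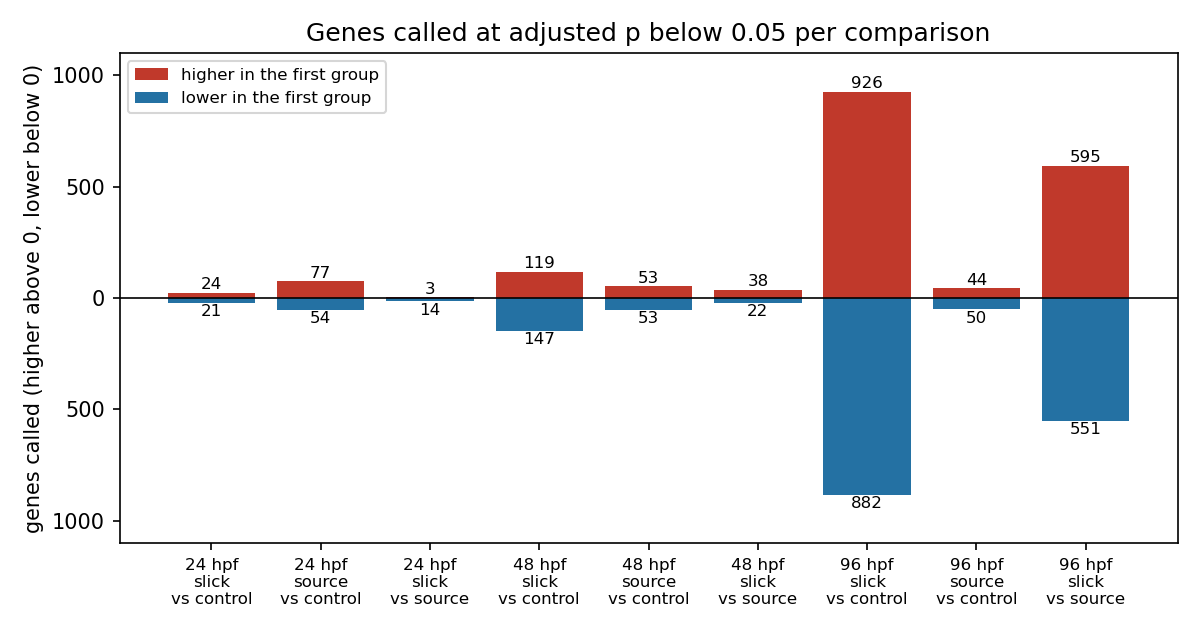
Number of genes called higher and lower (adjusted p below 0.05, edgeR) in slick against control, source against control and slick against source at 24, 48 and 96 hpf, with 3 libraries per group. The highest bars are those of slick against control at 96 hpf, with 926 genes higher and 882 lower, against 44 and 50 for source.

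At 96 hpf slick oil changed many more genes. Every one of 21 measured cholesterol biosynthesis genes rose (median log2 change 1.76, camera adjusted p = 2.1e-27; adjusted p = 0.028 with an estimated correlation). SQLE, the squalene epoxidase, rose 5.93-fold (136 ± 10.5 against 22.9 ± 2.97, adjusted p = 1.4e-30). MSMO1 rose 4.48-fold (2663 ± 153 against 594 ± 12.2, adjusted p = 1.8e-69) and LSS 3.88-fold. FGF7, a growth factor of epithelial cells, rose 12.1-fold (113 ± 12.2 against 9.94 ± 3.36, adjusted p = 4.5e-34). IGFBP1 rose 4.08-fold (278 ± 39.9 against 66.6 ± 13.3, adjusted p = 2.7e-34). In the insulin, glucose and lipid metabolism list, which camera did not call (4 higher and 5 lower of 21, adjusted p = 0.71), the lipid regulator SREBF1 (1.85-fold) rose, and ANGPTL4 fell to 0.651-fold.

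Phototransduction and lens genes fell in slick at 96 hpf. Camera did not call the 11 eye development genes, of which edgeR called 2 lower (median log2 change -0.12, camera adjusted p = 0.15). Of 23 phototransduction genes 20 fell, 1 rose and 2 were not called (median log2 change -1.24, camera adjusted p = 4e-20; adjusted p = 0.028 with an estimated correlation). The retinoid carrier RLBP1 was at 0.291-fold (142 ± 36.4 against 487 ± 31.7, adjusted p = 6.1e-39) and the cone arrestin ARR3 at 0.327-fold (119 ± 19.8 against 370 ± 30.8, adjusted p = 4.8e-33). PDE6G, a subunit of the photoreceptor phosphodiesterase, was at 0.34-fold and the cone opsin OPN1LW at 0.364-fold (2400 ± 311 against 6600 ± 359, adjusted p = 2.4e-51). All 10 lens genes fell (median -1.06, camera adjusted p = 2.3e-10; adjusted p = 0.12 with an estimated correlation). The crystallins were among them, with CRYBB2 at 0.298-fold (104 ± 33.2 against 346 ± 2.26, adjusted p = 8.2e-33), CRYBA4 at 0.4-fold (1066 ± 267 against 2657 ± 55.5, adjusted p = 3e-40) and CRYGB at 0.483-fold. Fish carry several opsins and crystallins of each kind, so these symbols may cover several genes, and each value comes from the 1 line kept. In the intestine list 5 of 6 brush border genes fell, and 6 adjusted over the list alone, including the peptidase ANPEP (0.481-fold, 391 ± 10.9 against 812 ± 34.4, adjusted p = 1.5e-29) and the peptide transporter SLC15A1 (0.491-fold; list median -0.99, camera adjusted p = 7e-06; adjusted p = 0.028 with an estimated correlation). Of 21 cartilage and bone genes 15 fell and 6 were not called, with 2 higher adjusted over the list alone. COL10A1, the collagen of hypertrophic cartilage, was at 0.478-fold (501 ± 35.3 against 1052 ± 57.2, adjusted p = 3.8e-31) and COL2A1 at 0.639-fold (median -0.46, camera adjusted p = 7e-06; adjusted p = 0.1 with an estimated correlation). Cell cycle genes fell in 10 of 20 cases, and 11 adjusted over the list alone, for example MCM2 (0.609-fold), MCM5 (0.643-fold) and TYMS (0.679-fold; camera adjusted p = 7e-06; adjusted p = 0.035 with an estimated correlation). The lists of erythroid genes (3 of 9 lower, among them the globin HBE1 at 0.6-fold; camera adjusted p = 0.022) and neuronal genes (6 of 19 lower and 1 higher, 9 and 1 adjusted over the list alone, with GRIN1 at 0.716-fold; adjusted p = 0.0047) were lower, with adjusted p = 0.1 and 0.16 with an estimated correlation. VWF, the endothelial and platelet adhesion protein, was at 0.326-fold (31.6 ± 8.39 against 94.9 ± 12.2, adjusted p = 1.6e-14).

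Genes of the NRF2, proteasome and innate immunity lists rose in slick at 96 hpf. Camera did not call the heat shock list (1 higher and 1 lower of 10, adjusted p = 0.82). Nor did it call the unfolded protein response list (2 lower of 15, adjusted p = 0.61). In the NRF2 list 8 of 13 genes rose, and 9 adjusted over the list alone (camera adjusted p = 5.4e-06; adjusted p = 0.035 with an estimated correlation). Among them were the autophagy receptor SQSTM1 (4.02-fold, 630 ± 67.3 against 155 ± 13.1, adjusted p = 5.3e-51), catalase (CAT, 1.55-fold) and PRDX1 (1.37-fold). Of 28 proteasome genes 23 rose and 5 were not called, with 24 higher adjusted over the list alone (median log2 change 0.29, camera adjusted p = 4.7e-09; adjusted p = 0.035 with an estimated correlation). PSMC4 rose 1.45-fold and PSMB7 1.41-fold. Innate immunity genes rose in 5 of 8 cases and fell in 1 (camera adjusted p = 0.00043; adjusted p = 0.035 with an estimated correlation). They included the macrophage gene MPEG1 at 3.37-fold, the prostaglandin synthase PTGS2 at 2.15-fold (207 ± 40.7 against 94.2 ± 9.78, adjusted p = 3.9e-16) and STAT3 at 1.76-fold. Lactate dehydrogenase (LDHA) rose 1.79-fold (936 ± 32.8 against 521 ± 36.1, adjusted p = 1.1e-24). It belongs to a hypoxia list with 4 higher and 1 lower of 15 members, 5 and 1 adjusted over the list alone (camera adjusted p = 0.0051; adjusted p = 0.057 with an estimated correlation). The AhR battery had 4 of 8 members higher (camera adjusted p = 3.9e-06; adjusted p = 0.042 with an estimated correlation). Ribosomal protein genes, with 23 of 61 higher, 27 adjusted over the list alone and 1 lower there (median 0.12, camera adjusted p = 0.00016), and oxidative phosphorylation genes, with 10 higher and 1 lower of 32, 11 and 1 adjusted over the list alone (median 0.10, adjusted p = 0.017), had adjusted p = 0.39 and 0.28 with an estimated correlation.

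Heart and muscle lists were not called by camera in slick at 96 hpf. Fry for a common direction gave adjusted p = 0.029 for cardiac sarcomere and 0.029 for calcium handling and ion channel genes. It gave 0.049 for cardiac development and 0.039 for fast muscle genes. Among 17 cardiac sarcomere genes 5 fell, including the atrial light chain MYL7 (0.237-fold, 6.23 ± 0.163 against 25.9 ± 4.09, adjusted p = 3e-07) and the myosin chaperone UNC45B (0.575-fold), and 3 rose, including MYL4 (1.6-fold; camera adjusted p = 0.19). Of 27 calcium handling and ion channel genes 8 fell, such as the L-type channel CACNA1S (0.711-fold), and the calcium store proteins CASQ1 (1.42-fold) and CASQ2 (1.35-fold) rose. Adjusted over the list alone 11 were lower and 2 higher (camera adjusted p = 0.056). In the cardiac development list 3 of 19 rose, among them GATA6 (1.33-fold) and BMP4 (1.31-fold), and MEF2C fell to 0.795-fold (camera adjusted p = 0.32). The apoptosis genes APAF1 (2.06-fold) and BAX (2.01-fold) were among 5 higher members of 11 p53 targets, with 1 lower (camera adjusted p = 0.06). Liver secreted proteins moved in both directions: prothrombin (F2, 1.73-fold) and RBP4 (1.43-fold) rose while TF (0.446-fold, 171 ± 13.8 against 389 ± 38.1, adjusted p = 3.5e-23) and FETUB (0.602-fold) fell. Across 8511 genes edgeR called 926 higher and 882 lower, of which 110 and 114 changed over 2-fold. Of all genes 2689 had an unadjusted p below 0.05 and 33.7% had separate groups against 10% by chance. DESeq2 called 1039, leaving out 1 library gave 1426 to 1707. MEF2C lost its call with 1 library left out and MYL4 with summed lines.

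**Figure D3:**
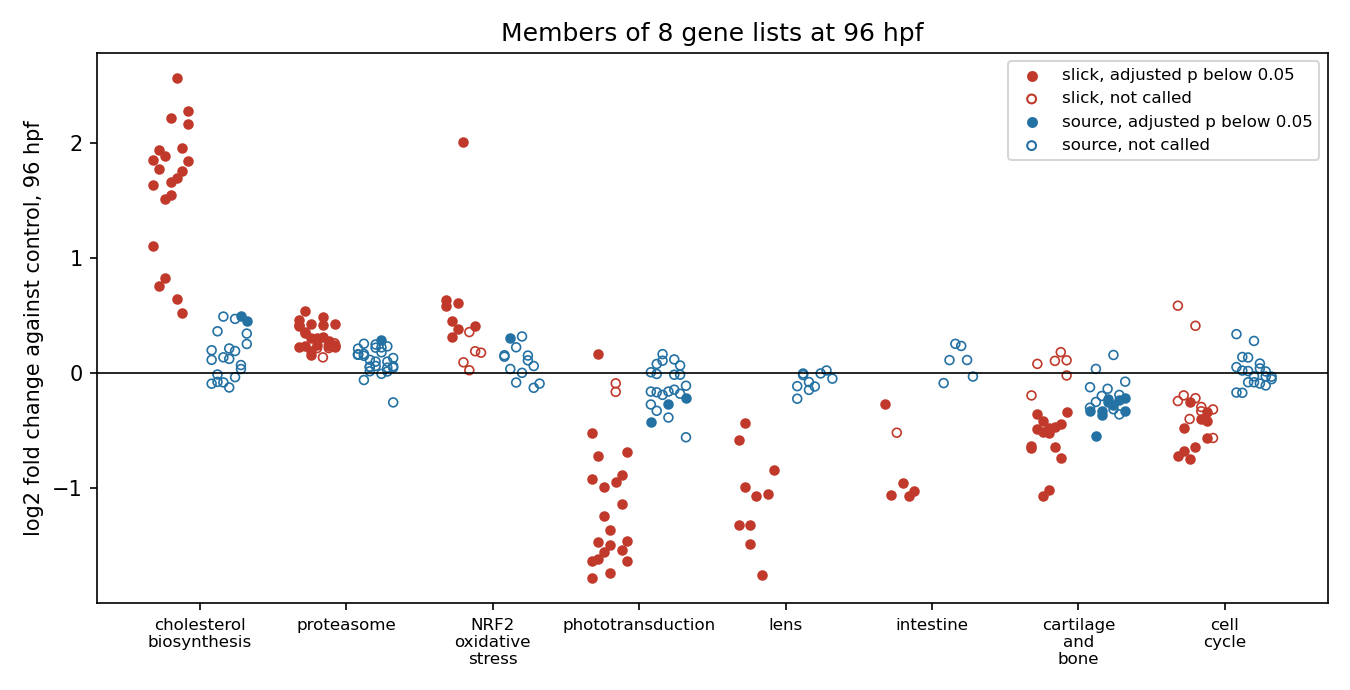
Log2 change at 96 hpf, against control, of each measured member of 8 gene lists in slick (red) and in source (blue), each point 1 gene, filled where the gene was called and open where it was not. The medians in slick are 1.76 for 21 cholesterol genes and -1.24 for 23 phototransduction genes, against 0.14 and -0.16 in source.

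Source oil at 96 hpf had smaller effects. PKHD1L1, a large membrane protein, rose 2.08-fold (517 ± 56.2 against 247 ± 26.9, adjusted p = 3.9e-23), and HPD, of tyrosine breakdown, 1.48-fold. CPS1, the carbamoyl phosphate synthetase of nitrogen metabolism (0.681-fold, 94.9 ± 6.58 against 137 ± 15.7, adjusted p = 0.002), the matrix gene MATN3 (0.687-fold) and DUS1L (0.681-fold) were lower. Liver secreted proteins rose in 4 of 13 cases and 8 adjusted over the list alone, with F2 at 1.47-fold (161 ± 5.4 against 110 ± 2.76, adjusted p = 0.00039), TF at 1.32-fold and the fibrinogen chain FGG at 1.26-fold (median log2 change 0.32, camera adjusted p = 3.2e-07; adjusted p = 0.046 with an estimated correlation). Cartilage and bone genes fell in 10 of 21 cases and 14 adjusted over the list alone, with COL2A1 at 0.795-fold (adjusted p = 6.9e-07) and COL11A2 at 0.829-fold (median -0.25, camera adjusted p = 3.2e-07; adjusted p = 0.18 with an estimated correlation). RLBP1 (0.748-fold, 364 ± 11.2, adjusted p = 6.7e-05), OPN1LW (0.862-fold) and GRK7 (0.833-fold) were the 3 lower members of 23 phototransduction genes, with 6 adjusted over the list alone (camera adjusted p = 0.0022; adjusted p = 0.43 with an estimated correlation). Higher lists included the AhR battery (4 of 8), cholesterol biosynthesis (2 of 21, MSMO1 at 1.37-fold and FDPS at 1.41-fold), exocrine pancreas (2 of 9, and 8 adjusted over the list alone, with CELA1 at 1.26-fold) and proteasome (1 of 28, and 5 adjusted over the list alone), with camera adjusted p = 5.6e-05, 0.00025, 0.00025 and 7.8e-05. They had adjusted p = 0.18, 0.36, 0.47 and 0.25 with an estimated correlation. The unfolded protein response list was higher by camera (median 0.18, adjusted p = 0.023; adjusted p = 0.36 with an estimated correlation) although its only called member, CHAC1, was lower (0.744-fold), with 2 higher and 1 lower adjusted over the list alone. None of 17 cardiac sarcomere genes was called by edgeR (camera adjusted p = 0.48). EdgeR called 44 genes higher and 50 lower. Of the genes tested 792 had an unadjusted p below 0.05, and 13.9% had separate groups against 10% by chance. The count of 94 fell to 50 without control replicate 10-11, to 62 without control replicate 12-13, to 46 without source replicate 17, to 49 with DESeq2 and to 10 with summed lines. HPD, MATN3, DUS1L, COL11A2, OPN1LW, GRK7, FDPS, CELA1, FGG and CHAC1 lost their calls with 1 library left out. With summed lines CPS1, TF, RLBP1 and COL1A1 (0.85-fold) lost theirs as well.

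Slick exceeded source at 96 hpf in all 21 cholesterol biosynthesis genes (median log2 difference 1.51, camera adjusted p = 3.6e-29; adjusted p = 0.023 with an estimated correlation), with SQLE at 4.27-fold and MSMO1 at 3.27-fold. FGF7 was 4.67-fold, IGFBP1 3.22-fold and SQSTM1 3.22-fold higher in slick. Phototransduction genes were lower in 19 of 23 cases and higher in 1 (median -1.14, adjusted p = 0.023 with an estimated correlation), with OPN1LW at 0.422-fold and PDE6G at 0.315-fold. The AhR battery (4 of 8 higher), NRF2 (7 of 13 higher), hypoxia (4 of 15 higher), innate immunity (5 higher and 1 lower of 8), cell cycle (10 of 20 lower) and intestine lists (5 of 6 lower) also held with an estimated correlation (adjusted p = 0.048, 0.043, 0.045, 0.045, 0.043 and 0.023). Calls of 4 further higher lists, for proteasome (8 of 28), ribosomal protein (10 of 61), fast muscle (5 of 14) and p53 target genes (5 of 11), were lost, as were those of 4 lower lists, for lens (9 of 10), neuronal (7 of 19), cartilage and bone (7 lower and 3 higher of 21) and unfolded protein response genes (3 of 15). They had adjusted p = 0.1, 0.49, 0.32, 0.1, 0.12, 0.12, 0.32 and 0.16 with an estimated correlation. EdgeR called 595 genes higher and 551 lower, 2098 had an unadjusted p below 0.05, and DESeq2 called 664. The fits that left out 1 library gave 866 to 1019.

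The overlap of slick and source calls was counted at each stage, where both oils were compared with the same controls. At 24 hpf 18 genes were called in the same direction (12 higher and 6 lower), at 48 hpf 53 (26 and 27) and at 96 hpf 72 (26 and 46). Independent lists would share 0.24 and 0.15, 0.78 and 0.97, and 4.8 and 5.2 genes. At 96 hpf 5 genes went opposite ways: AGXT, TF, MPO/EPX, PCK1 and MYOM3 were lower in slick and higher in source, a list chosen after its values were seen. The fold changes correlated across genes at 0.57, 0.50 and 0.43, against 0.52, 0.36 and 0.39 in 10 simulations in which no gene changed. Their covariance exceeded that of the same simulations without changed genes by 0.009, 0.015 and 0.022 (0.033, 0.028 and 0.036 against 0.024, 0.013 and 0.014). In 10 other simulations with shared controls, a test chosen after the counts were seen, the called changes of slick were put on their own genes. Those of source were put on other genes of like mean. They gave 0.6, 2.8 and 10 shared calls on average and at most 2, 5 and 15. The simulations draw genes independently, whereas genes of the real libraries are not independent replicates, and the controls were too few to be split, so a part of the excess may still come from them. CYP1A1, AHRR, FOXQ1, MEGF6 and LONRF1 were called higher, and MTHFD1, a folate enzyme, lower in slick at all 3 stages, and OGT was called at all 3 with a change of direction. In source CYP1A1 alone was called in the same direction at all 3, and SLC14A2 and COL11A2 were called at all 3 with a change of direction.

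Whether an oil's effect changed between stages was tested by interaction in 1 fit of all 27 libraries. From 24 to 48 hpf the slick effect on DDC, the aromatic amino acid decarboxylase, rose by 2.60 ± 0.37 (log2 ± standard error, n = 3 per group, adjusted p = 5.6e-07) and that on AHRR by 2.04 ± 0.48 (adjusted p = 0.013). That on G6PC fell by 1.88 ± 0.22 (adjusted p = 1.8e-09) and that on the calcium release channel ITPR3 fell by 1.05 (adjusted p = 0.0024). Of the 10 lists that camera called, the AhR battery (1 of 8 members called) and NRF2 (2 of 14) held, both upward, with an estimated correlation (adjusted p = 0.044 and 0.008). In all 60 genes passed the test, 17 upward and 43 downward. Left were 33 without 24 hpf control replicate 2, 34 by DESeq2 and 33 with summed lines. AHRR lost its call with 1 library left out. From 48 to 96 hpf the slick effect rose for 448 genes and fell for 588 (665 in all by DESeq2, and 852 to 1046 with 1 library left out). The cholesterol enzyme TM7SF2 rose by 1.88 ± 0.14 (adjusted p = 7.3e-20), IGFBP1 by 1.87 (adjusted p = 1.4e-08) and the fatty acid desaturase FADS6 by 1.78 (adjusted p = 1.7e-07), from lower than control at 48 hpf (-0.633, adjusted p = 0.00085) to higher at 96 hpf (1.19, adjusted p = 2.7e-05). RHCG fell by 1.99 ± 0.18 (adjusted p = 1.1e-15). The photoreceptor genes RGS9 and GNB3 fell by 2.50 ± 0.67 and 2.03 (adjusted p = 0.0053 and 0.0052), calls that were lost with 1 library left out. Camera called 18 lists, of which 8 held with an estimated correlation. Upward were those of cholesterol biosynthesis (19 of 21, median 1.56, adjusted p = 3e-06), proteasome (7 of 28, adjusted p = 0.0054), NRF2 (6 higher and 1 lower of 14, adjusted p = 0.014), innate immunity (3 of 8, adjusted p = 0.034) and liver secreted proteins (6 higher and 2 lower of 15, adjusted p = 0.038). Downward were those of phototransduction (7 of 23, median -1.07, adjusted p = 3.1e-05), intestine (0 of 6, adjusted p = 0.019) and cell cycle (7 of 22, adjusted p = 0.023). In 48 hpf controls 3 of the 23 phototransduction and 3 of the 6 intestine genes were at 0 counts. Within that stage 7 phototransduction genes could be tested, and the intestine list could not. For these 2 lists the interaction therefore sets the 96 hpf effect against few counts at 48 hpf. The source effect changed less between stages. From 24 to 48 hpf 0 genes went up and 13 down by edgeR, with 707 at an unadjusted p below 0.05 and 1 up and 9 down by DESeq2. G6PC fell by 1.05 (adjusted p = 0.019) and ETNPPL fell by 1.14 (adjusted p = 0.03), both lost with 1 library left out. CAPN9 fell by 0.71 (adjusted p = 0.00057). That count of 13 was 5 without 24 hpf control replicate 2, without 24 hpf source replicate 11 and without 48 hpf source replicate 15, and 31 without the low-count filter. No list held there with an estimated correlation, those of hypoxia (downward) and lens (upward) having adjusted p = 0.21 and 0.47. From 48 to 96 hpf 23 genes went up and 35 down, with F2 higher by 0.84 (adjusted p = 0.00018), DUS1L lower (-1.18, adjusted p = 0.0009) and RHCG lower (-0.95, adjusted p = 0.0059, lost with 1 library left out). Of 10 lists called there, cartilage and bone (9 of 21 downward, adjusted p = 0.027), liver secreted proteins (3 of 15 upward, adjusted p = 0.015) and proteasome genes (1 of 28 upward, adjusted p = 0.0042) held with an estimated correlation. The count of 58 was 34 without 48 hpf control replicate 4-5, 35 without 48 hpf control replicate 6-7, and 32 and 34 without 96 hpf control replicates 10-11 and 12-13. It was 34 without 48 hpf source replicate 13, 54 with DESeq2 (35 up and 19 down), 113 with the 32 samples as deposited (61 up and 52 down) and 11 with summed lines.

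Development of unexposed embryos gave the background for these effects. Between 24 and 48 hpf the fibrinogen gene FGB rose 37.5-fold (103 ± 7.54 against 2.66 ± 1.35) and the secreted inhibitor WFIKKN2 36.6-fold. DDC fell to 0.00511-fold (5.02 ± 1.13 against 1005 ± 6.95, adjusted p = 6.5e-66) and MPO/EPX, the granulocyte peroxidases, to 0.0355-fold. MPEG1 and the pancreatic CPA1, both at 0 counts at 24 hpf, rose at least 19.1-fold and at least 8.7-fold against a floor of 3 counts over the group. Neuronal genes rose in 14 of 19 cases (median log2 change 1.01, adjusted p = 0.0056 with an estimated correlation) and eye development genes in 10 of 12, with 1 lower (0.96, adjusted p = 0.0056). All 10 lens genes rose (3.72) and all 61 ribosomal protein genes fell (-0.51), each with adjusted p = 0.068 with an estimated correlation. The lists of fast muscle (10 of 15 higher and 4 lower), pigment cell (7 of 12 higher and 1 lower) and liver secreted genes (11 of 15 higher and 3 lower, median 1.09, and 0.76 with a gene at 0 at its bound) were called higher. Those of heat shock (7 of 10 lower, 1 higher) and unfolded protein response genes (10 of 15 lower, 1 higher) were called lower. None of these 5 lists held with an estimated correlation (adjusted p = 0.091, 0.12, 0.095, 0.068 and 0.12). Between 48 and 96 hpf the trypsinogen PRSS1 rose 577-fold (11530 ± 474 against 19.9 ± 1.02, adjusted p = 6.4e-97) with all 9 exocrine pancreas genes. TF fell to 0.0932-fold. COL10A1 and GRK7, at 0 counts at 48 hpf, rose at least 1540-fold and 695-fold. Phototransduction genes rose in 21 of 23 cases (median 6.15, and 6.03 with genes at 0 at their bound) and all 6 intestine genes rose (7.0, also at the bound). Neuronal genes rose in 17 of 19 and fell in 1, cholesterol genes rose in 17 of 21 and fell in 1. All 22 cell cycle genes fell (-1.35), and proteasome genes fell in 25 of 28 and eye development genes in 8 of 12. All of these held with an estimated correlation (adjusted p = 2e-05, 0.00024, 0.002, 0.044, 0.00066, 0.002 and 0.019; exocrine pancreas 2.4e-05), whereas lens (9 of 10 higher) and oxidative phosphorylation (17 of 32 higher) did not (adjusted p = 0.33 and 0.22). EdgeR called 2224 genes higher and 2035 lower from 24 to 48 hpf and 3109 and 2438 from 48 to 96 hpf, with 54.2% and 64.6% of genes in separate groups against 10% by chance. Leaving out 1 library gave 3744 to 4051 and 5185 to 5408.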

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

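The splits of the samples, the tests of developmental timing and the test of single slick libraries were chosen before their results were seen, and the tests of scaling, library size and labels, and the count of calls in unused table lines, after the result was seen.

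Oil effects that differed between stages by an interaction test were 60 genes for slick from 24 to 48 hpf, 1036 for slick from 48 to 96 hpf, 13 for source from 24 to 48 hpf and 58 for source from 48 to 96 hpf. Only 1 of 40 random splits of the libraries within stages, the real one, gave as many in each case, a share below 0.05. The splits exchanged oil and control libraries, which removes the oil effect itself. They therefore cannot tell whether that effect differed between stages. The highest other split gave 44, 867, 7 and 31, and was a split that kept the true groups of 1 stage. The slick effect from 24 to 48 hpf changed by 2.60 (log2) for DDC, 2.04 for AHRR, 0.98 for PISD, -1.88 for G6PC, -1.05 for ETNPPL and -1.05 for ITPR3. From 48 to 96 hpf it changed by 1.88 for TM7SF2, 1.87 for IGFBP1, 1.78 for FADS6, -2.50 for RGS9, -2.03 for GNB3 and -1.99 for RHCG. For source the change was -1.14 for ETNPPL, -1.05 for G6PC and -0.71 for CAPN9 from 24 to 48 hpf. From 48 to 96 hpf it was 3.87 for ASTL, 0.88 for BCO1, 0.84 for F2, -1.18 for DUS1L, -0.95 for RHCG and -0.85 for FNDC3B. DDC and ASTL fell in controls to 0.00511-fold between 24 and 48 hpf and to 0.00201-fold between 48 and 96 hpf, so their interactions compare stages with few counts. The fall of ASTL depends on the line kept, as it rose with summed lines (log2 1.78). AHRR, PISD, ETNPPL, G6PC in source, RGS9, GNB3, ASTL, BCO1, FNDC3B and RHCG in source lost the call with 1 library left out.

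Comparisons of 3 with 3 libraries have 10 splits, too few for a share under 0.05. The real split, which was 1 of 10 in every case, gave 45, 131, 17, 266, 106, 60, 1808, 94 and 1146 calls for slick against control, source against control and slick against source at 24, 48 and 96 hpf, and the highest other split 0, 7, 5, 11, 1, 8, 0, 2 and 0. For control development the values were 4259 and 5547 against 0 and 0.

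Table lines that the comparisons did not use, because their gene had a line with more counts, also held differences between oil and control. For slick 30, 361 and 1781 such lines were called at 24, 48 and 96 hpf, and for source 86, 88 and 92. The gene's used line was called too in 23, 274 and 1473 cases for slick and 72, 58 and 80 for source, and in 12 cases at 96 hpf in slick it went the opposite way. A total of 3, 47 and 183 genes in slick and 12, 19 and 6 in source were called by an unused line only.

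Lower eye genes in slick at 96 hpf: of 33 members of the phototransduction and lens lists 30 fell, with a median log2 change of -1.14, and at least 28 did so with any 1 slick library left out. With libraries scaled to total counts alone, which centres no median, it was -1.16 (95% bootstrap interval -1.49 to -0.937), so the choice of scaling is not the cause, though a shift of all genes alike cannot be seen in relative counts. A delay of the whole larva that lowered all genes rising between 48 and 96 hpf alike would lower genes matched on that rise in source libraries. These (166 in number) had a median of -0.14 (95% bootstrap interval -0.21 to -0.067), against -1.3 (-1.5 to -0.99) for the 24 eye genes that rise. That argues against such a uniform delay as the whole cause. The bootstrap intervals are over genes, which are not independent, so they do not measure the spread between libraries. Genes were matched on the size of the rise and not on its time between these stages, so an uneven delay stays open. A smaller delay also stays open as a part of the cause. Slick changes correlated with development at -0.18, and genes that rise or fall over 4-fold had slick medians of -0.21 and 0.21. A smaller eye or fewer photoreceptors and lens cells, and lower expression per cell, may each give this pattern, and whole larvae cannot tell them apart at a median of -1.14. The separate list of 11 eye development genes had a median of -0.12, with 2 called lower (camera adjusted p = 0.15).

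Higher cholesterol biosynthesis genes in slick at 96 hpf: all 21 rose, with a median log2 change of 1.76, and at least 20 did with any 1 slick library left out, so no single library carries the pattern. With total counts alone the median was 1.74 (1.52 to 1.86), which argues against the choice of scaling. Faster development is argued against by 120 matched genes outside the list with a median of -0.21 (-0.24 to -0.085), against 1.9 (1.6 to 2.1) for the 12 cholesterol genes that rise. These intervals too are over genes and not over libraries. A regulated response of sterol synthesis to slick oil is a hypothesis that these counts may fit, and neither sterol levels nor diet was measured here.

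Replicate 4 of slick at 48 hpf stood apart from replicates 5 and 6: leaving it out raised the calls of slick against source from 60 to 116. Its lower lens genes (median log2 difference -0.64) do not set it apart, as control replicate 6-7 differed from the other controls by -0.62. A wrong label is argued against by CYP1A1 and AHRR, which were 3 and 2.95 times the highest control or source library of the stage. Its total of 2497232 counts lay between those of replicates 5 (2560303) and 6 (2397977), so library size is not the cause. Developmental timing of the pool could not be settled: across 3187 genes its difference correlated at -0.094 (half-width 0.035) with the change of controls from 48 to 96 hpf. That value meets the bound set beforehand for excluding timing, but its interval reaches past the bound, so the reading was made more cautious after the value was seen.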

How the results depend on the processing

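The replicate block and all other settings here were planned except the 32 samples as deposited and the summed table lines, chosen after seeing the data. The cause of each change was not tested. Of the named genes' 505 calls, 505 were kept and 0 lost with 32 samples, 503 and 2 with RLE scaling, and 503 and 2 with no low-count filter. Of 307 within stages, 304 were kept and 3 lost with 1 surrogate variable, 300 and 7 with a robust fit, 292 and 15 with all libraries in 1 fit, and 301 and 3 with the 2 groups alone, where 3 had no result. DESeq2 kept 418 of 505 and lost 41, and 46 had no adjusted p there, among them 9 of 16 for slick and 14 of 22 for source at 24 hpf and 10 of 23 for source at 48 hpf. Summed lines kept 396 and lost 105, 3 had no result and 1 reversed (ASTL in controls from 48 to 96 hpf, log2 1.78 in place of -8.96). Over all fits, leaving out 1 library kept 3135 of 3474 calls and lost 339. Losses were uneven over the 6 such fits of each comparison with control. At 24 hpf 40 were lost for 16 named calls in slick and 34 for 22 in source. At 48 hpf 29 were lost for 39 in slick and 49 for 23 in source, and at 96 hpf 19 for 105 and 38 for 27. Control development lost 0. RLE scaling moved the split of higher and lower calls for source from 24 to 48 hpf to 2 and 15, and from 48 to 96 hpf to 27 and 27. All libraries in 1 fit moved that of slick at 96 hpf to 751 and 1066.

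Counts of called genes that moved over 1.5 times follow, with those given above in brackets. No low-count filter gave 110 (60) for slick against source at 48 hpf and 31 (13) for the source interaction from 24 to 48 hpf. A robust fit gave 160 (106) for source and 100 (60) for slick against source at 48 hpf. All libraries in 1 fit gave 18 (45) for slick and 10 (17) for slick against source at 24 hpf. The 2 groups alone gave 181 (106) for source at 48 hpf. DESeq2 gave 84 (131) for source and 5 (17) for slick against source at 24 hpf. At 48 hpf it gave 124 (266), 57 (106) and 37 (60) for slick, source and slick against source. It gave 1039 (1808), 49 (94) and 664 (1146) at 96 hpf, and 34 (60) and 665 (1036) for the slick interactions. The 32 samples gave 182 (106) for source at 48 hpf and 22 (13) and 113 (58) for the source interactions. Summed lines gave 6 (45), 44 (131) and 3 (17) at 24 hpf and 148 (266), 34 (106) and 27 (60) at 48 hpf. They gave 10 (94) for source at 96 hpf, 33 (60) for slick from 24 to 48 hpf and 11 (58) for source from 48 to 96 hpf.

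Leaving out 1 library gave 16 to 45 calls for slick, 53 to 111 for source and 4 to 20 for slick against source at 24 hpf. At 48 hpf it gave 170 to 285, 26 to 101 and 33 to 116, and at 96 hpf 1426 to 1707, 46 to 105 and 866 to 1019. The interactions gave 33 to 74 and 852 to 1046 for slick and 5 to 17 and 32 to 76 for source, and control development 3744 to 4051 and 5185 to 5408.

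The replicate block could be fitted for slick against control at 24 hpf, the only groups sharing numbers once pairs were summed. Fitted with the 2 groups alone, it gave 71 calls (30 higher and 41 lower) and kept all 16 named genes. The 2 groups alone without a block gave 44 calls, and the fit of the whole stage 45. Deviations from the group means correlated across genes at 0.03, -0.0076 and 0.034 for libraries of the same number. For libraries of different numbers they correlated at -0.037 to 0.008. With 3 pairs these values cannot tell whether samples of the same number share more than that number. The planned block at 48 hpf and the split of the controls were not run, as too few libraries remained.

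Lists called by camera numbered 4, 7 and 5 at 24 hpf, 7, 9 and 13 at 48 hpf and 15, 8 and 16 at 96 hpf (slick, source, slick against source). They were 10 and 18 for slick and 2 and 10 for source interactions, and 9 and 10 in development. In the same order an estimated correlation gave 1, 0 and 0, 1, 0 and 2, 8, 1 and 8, 2 and 8, 0 and 3, and 2 (and 8). Fry for a common direction moved the count to 1, 3 and 1 at 24 hpf and 3 for source at 48 hpf. It moved to 24 and 2 for slick and source at 96 hpf, 6 for slick from 24 to 48 hpf, 1 and 3 for source interactions, and 25 and 27 in development. Fry for either direction gave 10 and 14 for slick and source at 24 hpf, and 15 for slick at 48 hpf. It gave 29 for slick and 27 for slick against source at 96 hpf, 5 for source from 24 to 48 hpf, and 29 and 31 in development. No filter gave 1 for slick against source at 24 hpf and 4 for source from 24 to 48 hpf. Beyond the self-test's shares, depth limits genes with few counts, such as AHRR and CYP1B1 in controls.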

Other observations

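These groups of genes were chosen after their values were seen. No list of nitrogen genes was tested, so the genes of this paragraph stand singly. At 48 hpf slick oil raised 3 ammonia channel genes, RHCG (log2 change 1.58 ± 0.16, standard error, n = 3, edgeR adjusted p = 3.8e-10), RHBG (1.33 ± 0.10) and RHAG (1.14 ± 0.09). In source RHBG was higher by 0.67 (adjusted p = 0.00046) and RHCG by 0.78 (adjusted p = 0.023, lost in 3 of 6 fits with 1 library left out). RHAG differed there by 0.27 without passing the test (adjusted p = 0.21). At 96 hpf RHCG was lower in slick (-0.36, adjusted p = 1.1e-05) and RHBG higher (0.30). RHAG was higher by 0.21 in slick (adjusted p = 0.0058, called in 4 of 6 fits with 1 library left out) and by 0.27 in source (adjusted p = 0.0043, called in 3 of 6). SLC14A2, a urea transporter, was higher in source at 24 hpf (1.63, adjusted p = 0.00081, called in 6 of 6 fits with 1 library left out). At 48 hpf it was lower in slick (-2.09, adjusted p = 9.1e-08) and in source (-1.76, adjusted p = 1.6e-05). At 96 hpf its slick libraries held 2 counts against 180 in controls, a ratio of 52.7 with a 95% counting interval of 14.4 to 439. Source was lower by less (-1.07, adjusted p = 0.002). The urea cycle genes CPS1 (-1.25, adjusted p = 2.3e-14) and ASS1 (-1.34, adjusted p = 8.9e-22) were lower in slick at 96 hpf. The arginase gene ARG2 was higher (1.02, adjusted p = 9.3e-06), while OTC was not called (-0.42, adjusted p = 0.1). CPS1, ASS1 and ARG2 were not called in either oil against control at 24 or 48 hpf, and GLUL was called in neither oil at any stage.

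Lipid genes outside the cholesterol list did not all follow it in slick at 96 hpf. The desaturase gene FADS6 rose most (log2 change 1.19, adjusted p = 2.7e-05, called in 6 of 6 fits with 1 library left out), after lower counts in slick at 48 hpf (-0.633, adjusted p = 0.00085, also in 6 of 6). INSIG2, a brake on the pathway (log2 change 0.75, adjusted p = 2e-08), and ACLY, which supplies acetyl-CoA (0.37, adjusted p = 1e-06), were higher. The lysosomal cholesterol exporter NPC1 (0.55, adjusted p = 0.0012) and ACACB (0.31, adjusted p = 0.00057) were higher too. LPIN1, a phosphatidate phosphatase, was lower (-0.82, adjusted p = 2.9e-13), and FASN, the fatty acid synthase (-0.06, adjusted p = 0.83), and ACACA (0.15, adjusted p = 0.16) were not called. The cholesterol exporter ABCA1 (-0.10, adjusted p = 0.21) and the bile acid enzyme CYP7A1 (-0.07, adjusted p = 0.45) were not called either. Of the genes that slick changed at all 3 stages, MEGF6 was higher by 0.42, 0.69 and 1.36 and LONRF1 by 0.47, 0.51 and 0.61, and MTHFD1 was lower (-0.26, -0.31 and -0.58) at 24, 48 and 96 hpf. At 24 hpf each of these 3 was called in 2 of 6 fits with 1 library left out, and MTHFD1 at 48 hpf in 3 of 6.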
